A study of Homo sapiens with 10 samples.

How the data were processed

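RNA from A549 cells was measured on Illumina bead arrays in 10 samples, 5 from cells given crystalline silica at 50 µg/ml and 5 from cells given 0 µg/ml, all collected after 6 h, per the labels. The RNA was copied into biotin-labelled cRNA and hybridised, per the labels' protocols. Each sample was placed in its group by the dose in its own label, and the replicate numbers were taken as names of samples. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

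The scanner table deposited by the authors holds, for each array, an average bead intensity on a linear scale, the standard error of the bead intensities, the number of beads and a detection p-value, per the file headers. The submitters' processing notes name BeadStudio, lumi and limma, with no version or setting. The table has 37846 rows, mostly 1 per gene. Its bead numbers are not whole in the rows that hold several probes, so the deposited intensity of such a row is an average over probes. A row was taken to hold 1 probe where its bead number was whole within 1e-06 on every array and its detection p-value lay within 0.005 of the curve relating p-value to intensity, which gave 30869 rows, and the other 6977 were taken to hold several. In the latter the detection p-value that the authors deposited follows the intensity loosely, and bright genes can have a p-value above 0.01. Genome build and array version were not given in the sources used here, so no coordinates are printed and chromosomes are those of the deposited table.

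The authors also deposited a processed table of 13297 rows on a log2-like scale. All of them had a detection p-value under 0.01 in 1 or more arrays, a property of 13298 rows of the scanner table. Each column correlated best with its own array's log2 intensity, at 0.762 to 0.973, with slopes of 0.439 to 0.576 over the dimmer genes and 0.978 to 1.09 over the brightest. Column medians lay between 7.41 and 7.43. The values are not centred per gene and run in the same direction as the intensity, while the exact transform and the normalization stay unknown. They served as an alternative only.

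The analysis started from the deposited intensities. Background was corrected with normexp in limma 3.58.1 (R 4.3.3), with the mean and spread of the negative controls inferred from the detection p-values, since the negative controls themselves were not used here. The inference was restricted to rows taken to hold 1 probe. This restriction was chosen after seeing the data, because inference from all rows placed the background above the median of all genes, and inference from all rows was kept as an added alternative. An offset of 16 was added, arrays were quantile normalized, and values were put on the log2 scale. Folds of dim genes depend on this correction and offset, and are smaller without it. A gene was tested where its detection p-value was under 0.01 in at least 5 of the 10 arrays, whatever the group. This left 8433 rows, and where 2 or more rows carried the same gene the brightest was kept, which removed 28 rows and left 8405 genes. Gene symbols were updated through the Entrez gene ID for 7785 genes and through the accession for 9, from the RefSeq table of assembly GRCh38.p14, and 611 kept the name in the deposited table. Updated names differ from the deposited ones for 1599 genes, for example CXCL8, which is IL8 there.

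Silica was compared with control by lmFit and eBayes of limma with Benjamini-Hochberg adjustment over all genes tested, and genes with an adjusted p under 0.05 were called changed. Fold changes are silica over control. A gene that passed detection on no array of a group has only a bound there. Its fold is given as at least the silica mean over the control mean in which each array's value was raised to the lowest value of any detected row. The rows of several probes make this floor approximate. Gene lists were tested with camera at a preset correlation of 0.01, with the correlation estimated from the data as an alternative, and with fry, which tests whether the genes of a list move one way on balance. Lists needed 3 tested genes, and p-values were adjusted over the lists. Some lists share members, so their calls are not independent. TNFRSF10B and PMAIP1 are in both the p53 target and the BCL2 family lists, and IER3 is in both the ERK feedback and the NF-kB lists.

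The groups, the test, the 30 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named the 12 largest rises and the 12 largest falls among called genes whose 5 silica values all lay on one side of the 5 control values, leaving out provisional symbols. It also named up to 3 called members of each tested list, or the member with the smallest p where none was called, and CXCL8, IL6, HMOX1 and FOS whatever their values. The provisional gene HS.526470 was called but falls outside the rule, and it is named, after its values were seen, because so few genes fell. Some further genes are not reported here, though the counts include them. Further list members that passed when adjusted over the list alone are named after their values were seen. Adjustment over a list alone does not correct for the 28 lists tested. None of the members named only on that adjustment passed over all genes.

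The alternatives were no background correction, normexp with an offset of 50, median centring, the authors' processed values, no detection filter, detection in all 10 arrays, the mean over rows of a gene, the replicate number as a block, array weights, trended and robust variances, a stricter adjusted p of 0.01, and each array left out in turn. A block for the chip was not run, because the chip of each array was not given in the sources used here. After seeing the data 6 more were added, for the arrays that stood apart, for the rows that set the background and for the filter. The steps were tested on simulated arrays with 200 changed genes among 10703 tested. The fit recovered 34% of genes changed 1.5-fold, 76% at 2-fold, 94% at 3-fold and 100% at 4-fold, and 6.75% of its 163 calls were false. Of 580 random gene lists, 0 were called, and 20 of 20 lists in which 5 of 15 genes rose 2-fold were called. Genes were simulated independently of each other, so these list results do not cover lists of correlated genes. Changed genes were drawn from brighter rows and every row was treated as 1 probe, so the recovery does not cover dim genes such as FOS. The simulation made 163 calls where the comparison made 16, so its Benjamini-Hochberg cutoff on the unadjusted p was looser. Its recovery is therefore not the power of the comparison itself. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.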

Results

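A549 cells, a line from a human lung adenocarcinoma used as a model of alveolar epithelium, were exposed for 6 h in serum-free medium to crystalline silica, the mineral dust whose inhalation causes silicosis. The comparison asks which transcripts changed in cells given silica at 50 µg/ml (n = 5) relative to cells given 0 µg/ml (n = 5), as part of work on how silica is toxic to the lung. On each array 8210 to 9118 of 37846 rows were detected, a row's signal rested on a median of 16.5 to 20 beads, and 8405 genes were tested. The number of arrays limits the precision, and the median pooled SD of a gene within the groups was 0.26 on the log2 scale.

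Silica raised a small set of stress and inflammatory genes. The largest rise was that of FOSB, an AP-1 transcription factor subunit, which rose 8.39-fold (log2 fold change 3.07 ± 0.17 SE, limma adjusted p = 9.49e-07). CXCL8, the neutrophil-attracting chemokine interleukin-8, rose 3.89-fold (1.96 ± 0.13 SE, limma adjusted p = 7.37e-06), and EGR1, a zinc finger transcription factor of the immediate early response, rose 3.95-fold (1.98 ± 0.20 SE, limma adjusted p = 0.000539). The sizes depended on the background correction, with log2 fold changes over 26 alternatives of 1.84 to 3.25 for FOSB, 1.66 to 2.60 for CXCL8 and 0.69 to 2.08 for EGR1. Over all 8405 genes 16 changed, of which 14 rose and 2 fell, each by at least 1.5-fold, and for each of the 16 the 5 silica values lay entirely on one side of the 5 control values. Such separation was seen for 125 genes in all (1.49%, where chance gives 0.794%), 66 higher and 59 lower with silica. At an unadjusted p under 0.05 there were 505 genes, against 420.25 expected by chance.

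**Figure D1:**
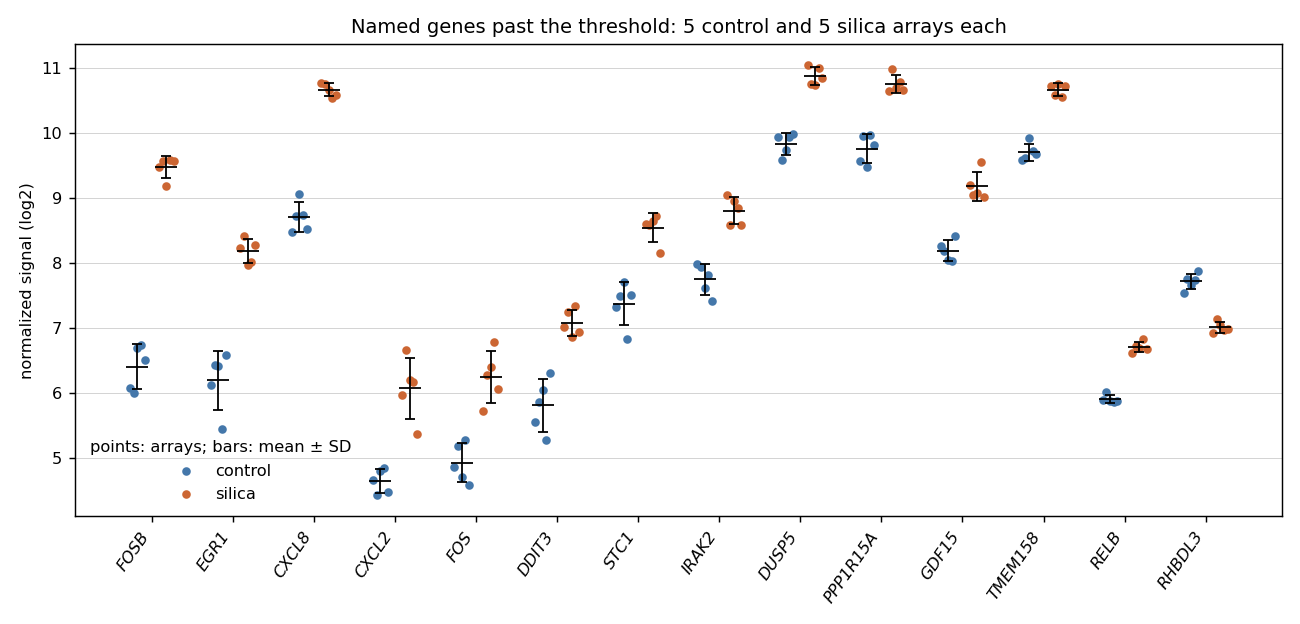
Normalized log2 signal (y axis) of 14 of the genes that passed the threshold, those that the naming rule takes (x axis), ordered by log2 fold change, with 1 point per array for the 5 control and 5 silica arrays and bars for mean ± SD. FOSB has control values of 6.00 to 6.74 and silica values of 9.19 to 9.59, and the groups do not overlap for any gene shown.

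The other genes that rose included DDIT3, which encodes the stress transcription factor CHOP, and PPP1R15A, which directs dephosphorylation of the translation factor eIF2-alpha. DDIT3, detected in 4 of 5 control arrays, rose 2.41-fold (limma adjusted p = 0.00951) and PPP1R15A 1.99-fold (limma adjusted p = 0.00629). IRAK2, a kinase of interleukin-1 and Toll-like receptor signalling, rose 2.07-fold and RELB, an NF-kB subunit, 1.74-fold (limma adjusted p = 0.00756 and 0.00522). DUSP5, a phosphatase that inactivates ERK in the nucleus, rose 2.05-fold, and TMEM158, a membrane protein induced by RAS signalling, rose 1.95-fold (limma adjusted p = 0.00253 for both). GDF15, a secreted cytokine of the TGF-beta superfamily induced by cell stress, rose 1.99-fold (limma adjusted p = 0.00727), and the secreted glycoprotein hormone STC1 rose 2.25-fold (limma adjusted p = 0.00951). Over the alternatives the log2 fold changes ran from 0.22 to 1.40 for DDIT3, 0.12 to 0.84 for RELB and 0.71 to 1.27 for STC1, with 0.61, 0.37 and 0.85 without background correction. FOS, the partner of JUN in AP-1, passed detection on none of the 5 control arrays and all 5 silica arrays and was at least 1.81-fold higher (limma adjusted p = 0.0117). CXCL2, another neutrophil chemokine, was likewise at least 1.61-fold higher (limma adjusted p = 0.00756). Both bounds hold only for the main background correction. Over 25 alternatives the log2 fold changes ran from 0.13 to 1.45 for FOS and 0.13 to 1.60 for CXCL2. Without background correction they were 0.50 and 0.54, and neither gene was called (limma adjusted p = 0.0927 and 0.0622).

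The genes that fell were RHBDL3, a rhomboid-like membrane protein encoded on chromosome 17, and HS.526470, a transcript with a provisional name on chromosome 15. RHBDL3 fell by 0.70 on the log2 scale (0.614 of control, limma adjusted p = 0.0170) and HS.526470 fell by 0.93 (0.526 of control, limma adjusted p = 0.0190). RHBDL3 lost its call when control 2 or 5 or silica 1, 3, 4 or 5 was left out (log2 fold change -0.71 to -0.66, limma adjusted p = 0.0627 to 0.0853), and HS.526470 when control 1 or 2 or silica 2, 3 or 4 was left out (-0.91 to -0.86, limma adjusted p = 0.0701 to 0.0851). FOS lost its call without silica 3 (1.28, limma adjusted p = 0.0533). Each of RHBDL3 and HS.526470 was called in 16 of 26 alternatives, with log2 fold changes of -0.75 to -0.25 and -1.01 to -0.60.

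Of the 28 gene lists with enough tested members, 14 were called by camera, 9 higher and 5 lower with silica. The immediate early and AP-1 genes were higher as a list (median log2 fold change 0.32, camera adjusted p = 3.05e-11, adjusted p = 0.00164 with an estimated correlation). Of its 17 tested members 3 rose over all genes and 8 when adjusted over the list alone, and none fell. Besides FOSB, EGR1 and FOS these were ZFP36, which promotes decay of cytokine mRNAs (1.51-fold), JUN (1.35-fold), NR4A2 (1.64-fold, detected in 2 control and 4 silica arrays), KLF2 (1.44-fold) and BHLHE40 (1.25-fold). From ZFP36 to BHLHE40, limma adjusted p over all genes was 0.320 to 0.712. The ERK pathway feedback genes were also higher (median 0.23, camera adjusted p = 5.03e-05, adjusted p = 0.0124 with an estimated correlation), with 1 of 13 members past the threshold over all genes and 3 adjusted over the list alone. These were DUSP5, IER3 (1.37-fold), an early response gene that modulates cell survival, and PHLDA1 (1.41-fold).

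The cytokines and chemokines were higher as a list (median 0.49, camera adjusted p = 1.62e-09, adjusted p = 0.0116 with an estimated correlation). Of 10 tested members 2 rose over all genes and 6 adjusted over the list alone. Beyond CXCL8 and CXCL2 these were IL6, CCL2, CXCL5 and VEGFC. CCL2, which attracts monocytes, had a log2 fold change of 1.14 ± 0.31 SE (limma adjusted p = 0.433 over all genes). IL6, the acute phase cytokine, had 0.80 ± 0.19 SE (limma adjusted p = 0.320 over all genes) and was detected in 1 of 5 control arrays and 5 of 5 silica arrays. The NF-kB feedback and target genes were higher (median 0.14, camera adjusted p = 0.00190), a call not held with an estimated correlation (adjusted p = 0.0511 with an estimated correlation). Of 21 tested members 2 rose over all genes, RELB and IRAK2, and 5 adjusted over the list alone, which added PTGS2, the inducible cyclooxygenase (1.88-fold, detected in 4 of 5 control arrays), IER3 and BIRC3, an inhibitor of apoptosis (1.42-fold).

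The list of ATF4 and amino acid response genes was higher (camera adjusted p = 0.00752, adjusted p = 0.116 with an estimated correlation), although its median was only 0.04. Of its 20 tested members 2 rose over all genes, DDIT3 and PPP1R15A, and 4 adjusted over the list alone, which added TRIB3, a pseudokinase that inhibits AKT (1.69-fold), and the secreted STC2 (1.50-fold). The ER chaperone genes, which the unfolded protein response also induces, were not called (17 tested, median 0.04, camera adjusted p = 0.887). None of them passed over all genes or adjusted over the list alone, and the member with the smallest p, HERPUD1, had a log2 fold change of 0.30 ± 0.11 SE.

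The p53 target genes were higher as a list (15 tested, median 0.10, camera adjusted p = 0.0115, adjusted p = 0.114 with an estimated correlation), with GDF15 the only member past the threshold over all genes or adjusted over the list alone. The BCL2 family and death receptors were higher (10 tested, median 0.19, camera adjusted p = 0.0115, adjusted p = 0.0802 with an estimated correlation). None of its members passed over all genes and 1 did adjusted over the list alone, the anti-apoptotic MCL1 (1.51-fold). Without control 5 neither list was called (p53 median 0.13, adjusted p = 0.0574; BCL2 median 0.10, adjusted p = 0.0643), the highest adjusted p of each over 26 alternatives, with lowest values of 0.00358 and 0.00212. EGFR ligands and the plasminogen system were higher (10 tested, median 0.24, camera adjusted p = 0.0115, adjusted p = 0.0802 with an estimated correlation), with 0 members past the threshold over all genes and 1 adjusted over the list alone, HBEGF, a ligand of the EGF receptor (1.65-fold). Members of this list lay at a median of -0.37 in control 4 relative to the other controls. Without control 4 the list was not called (median 0.08, camera adjusted p = 0.0788, range over 26 alternatives 0.000200 to 0.305).

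Heat shock genes were lower with silica (19 tested, median -0.17, camera adjusted p = 0.00347, adjusted p = 0.114 with an estimated correlation). None passed over all genes, and 1 fell adjusted over the list alone, HSPA1B, an inducible HSP70 chaperone (log2 fold change -0.47 ± 0.11 SE, limma adjusted p = 0.310 over all genes). With median centring the list was still called (camera adjusted p = 0.0308, range over 26 alternatives 0.000284 to 0.0536), with a median of -0.02. The median of all tested genes was 0.09 in that setting, and list medians there are to be read against it. Cell cycle lists were lower, the G1/S and DNA replication genes with a median of -0.08 (25 tested, camera adjusted p = 0.0117, adjusted p = 0.324 with an estimated correlation) and the G2/M genes with a median of -0.13 (28 tested, camera adjusted p = 0.0174, adjusted p = 0.187 with an estimated correlation), but with median centring the medians were 0.02 and 0.01 and neither list was called. No member of either list passed over all genes or adjusted over the list alone. The G2/M member with the smallest p was the mitotic kinesin KIF11 (-0.32 ± 0.13 SE). Control 4 lay high for both lists, with median deviations of 0.23 and 0.30 from the other controls. Without control 4 neither list was called (medians -0.05 and -0.10, camera adjusted p = 0.171 and 0.0956). Without control 1 the G2/M list also lost its call (median -0.15, adjusted p = 0.0569). Over 26 alternatives adjusted p ran from 0.00324 to 0.598 for G1/S and from 0.00877 to 0.218 for G2/M.

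The alveolar and airway epithelial markers were lower (9 tested, median -0.10, camera adjusted p = 0.0456, adjusted p = 0.116 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone. E-cadherin, CDH1, had a log2 fold change of -0.39 ± 0.16 SE. Fibroblast markers, of which 4 were tested, were lower (median -0.31, camera adjusted p = 0.0426, adjusted p = 0.116 with an estimated correlation), with 0 members past the threshold over all genes and 2 that fell adjusted over the list alone, the collagen chains COL1A1 (-0.53 ± 0.16 SE) and COL5A1 (-0.57 ± 0.18 SE). Both calls depended on single arrays. With median centring the epithelial median was -0.01, against 0.09 for all tested genes, and the list was not called (camera adjusted p = 0.0953). The epithelial call was lost without control 1, 3, 4 or 5 or silica 1, 4 or 5 (medians -0.13 to -0.07, adjusted p = 0.0574 to 0.121), and the fibroblast call without control 1, 2, 3 or 5 or silica 1, 3 or 4 (medians -0.33 to -0.23, adjusted p = 0.0616 to 0.114). Over 26 alternatives adjusted p ran from 0.0142 to 0.306 and from 0.00641 to 0.159. Macrophage markers (2 tested) and endothelial and lymphocyte markers (1 tested) had too few members for a test.

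The ribosomal protein genes were higher as a list (31 tested, median 0.17, camera adjusted p = 0.00347, adjusted p = 0.444 with an estimated correlation), with no member past the threshold over all genes or adjusted over the list alone. These genes lay at a median of -0.65 in control 4 relative to the other controls. Without control 4 the median was 0.02 and the list was not called (adjusted p = 0.680; range over 26 alternatives 8.29e-05 to 0.815).

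**Figure D2:**
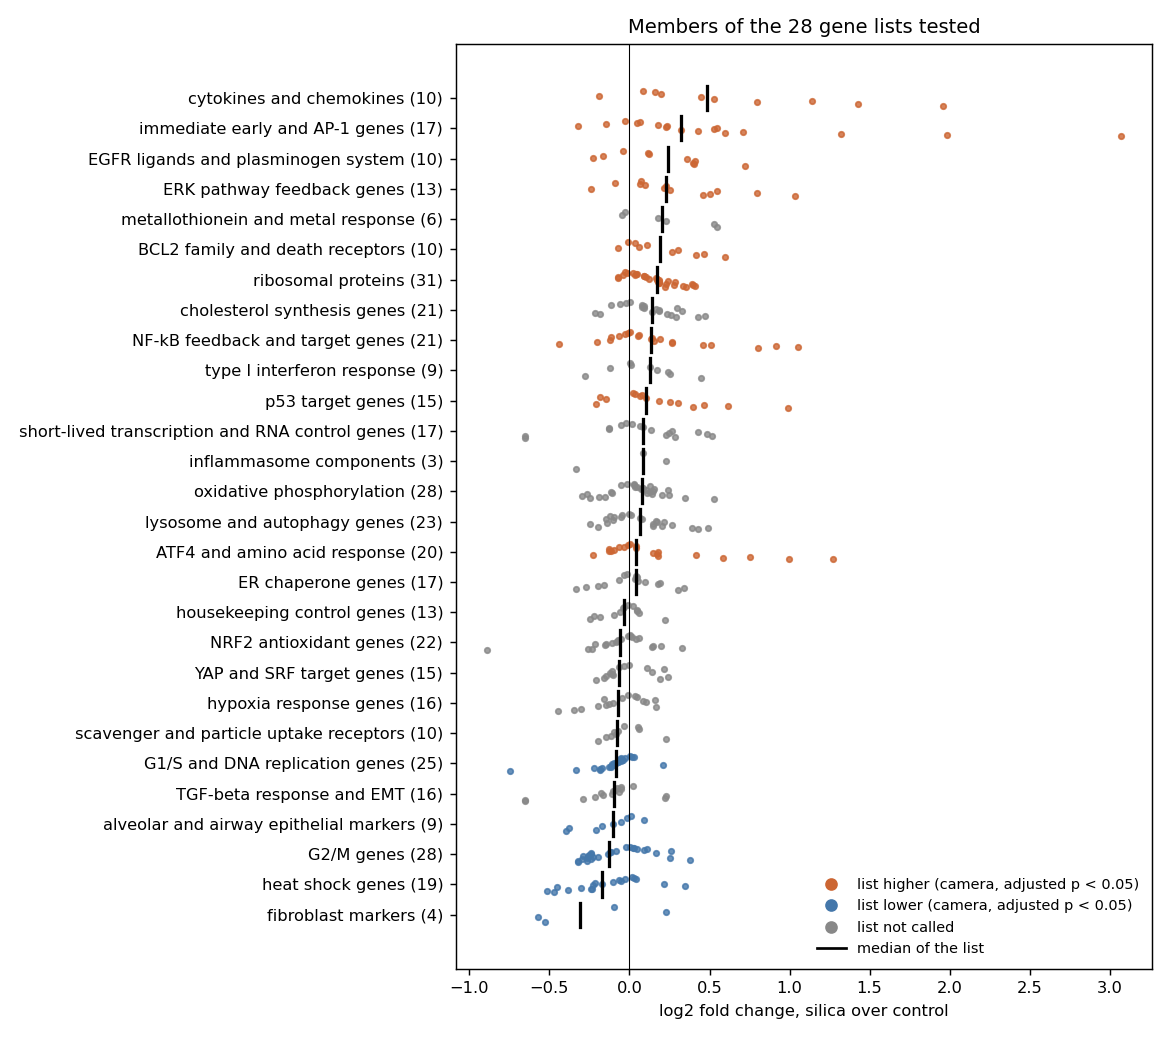
Log2 fold change, silica over control (x axis), of the tested members of 28 gene lists (y axis, number of tested members in brackets), with 1 point per gene and a black line at each list's median. Colours mark lists called higher or lower by camera, and the cytokine list has the highest median, 0.49.

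Some arrays stood apart from the rest. Control 4 correlated with the others at 0.944 to 0.952, where the other 9 arrays correlated with each other at 0.973 to 0.987, and without it 18 genes were called, 15 of them shared with the 16, and 10 lists, 9 of them shared with the 14. Control 3 and silica 4 had median signals of 209 and 199, against 68.2 to 76.2 on the other 8 arrays. With these 2 bright arrays as a block 16 genes were called, 15 of them shared with the 16. Each of the 16 genes had the same direction within the bright pair and within the other 8 arrays. This follows from groups that do not overlap, so it does not bear on brightness. The other 8 arrays alone gave 5 calls, among them FOSB, CXCL8, EGR1 and TMEM158. The 11 genes that lost their calls there kept 85.7% to 103% of their log2 fold change (limma adjusted p = 0.0560 to 0.135). Median centring in place of quantile normalization left 3 calls, FOSB, CXCL8 and EGR1, with 3 higher and 0 lower, while the 13 genes that lost their calls kept 86.0% to 112% of their log2 fold change. The calls of FOS and CXCL2, which were undetected in controls, were not held in the authors' processed values (log2 fold change 0.31 for both, limma adjusted p = 0.215 and 0.187), and they were called in 17 and 19 of the 25 alternatives that tested them.

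**Figure D3:**
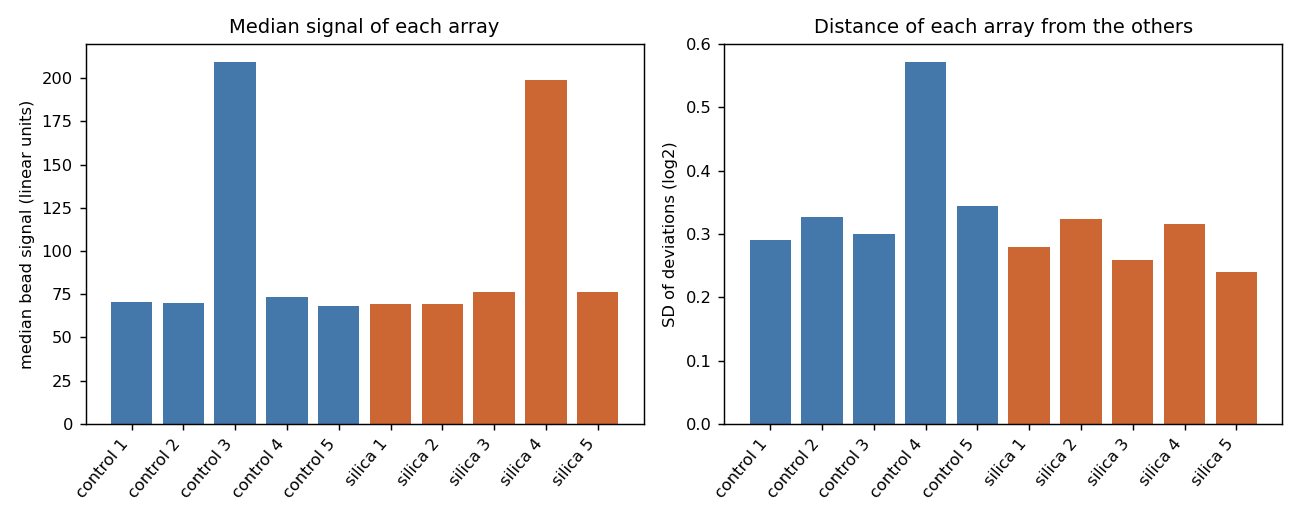
Median bead signal in linear units (left) and SD of each array's log2 deviations from the other arrays (right) for the 5 control and 5 silica arrays, with 1 bar per array. Control 3 and silica 4 reach median signals of 209 and 199, and control 4 has the largest SD, 0.57.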

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

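The tests on control 4, on the lists it moves and on pairs without a bright array were chosen after the result was seen, while the tests over regrouped arrays and over all removed pairs were set before. Among 86 groups of 5 arrays, 13 held 1 array far from the rest, where chance gives about 4.3 (1 group in 20).

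For control 4 the mean correlation with the other arrays was 0.948, against 0.973 to 0.976 for the other controls, and the SD of its log2 deviations was 0.57, against 0.29 to 0.34. Its lower number of beads as the source is argued against by the size of that SD, 1.95 times the median of the other 9 arrays, while the bead numbers allow 1.10. A silica array carrying a control label is argued against by its mean position of 0.0323 on a scale from control (0) to silica (1) over the genes called without it. Its deviations rose with genomic gene length (Spearman rho 0.375 across genes, which are not independent replicates, against -0.08 to 0.09 on the other arrays), from a median of -0.49 in the shortest 10% of genes to 0.26 in the longest 10%, over the 92.8% of tested genes with a length. Loss of short transcripts in this sample is a candidate explanation, with genomic length as a stand-in for transcript length, and a biological difference of this sample stays open, since no group in the design bears on it.

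The ribosomal protein list, made up of short and abundant transcripts, was called higher with silica. Without control 4 its median was 0.0176, which is consistent with that array alone as the source of the call. For heat shock genes the same explanation is argued against, as the median without control 4 was -0.13 and the list was still called (camera adjusted p = 0.00351, range over 26 alternatives 0.000284 to 0.0536). However, with median centring and all arrays the median was -0.02, against 0.09 for all tested genes. No biological explanation of the heat shock difference was tested beyond the silica grouping itself.

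Median signal was 209 on control 3, against 68.2 to 73.4 on the other controls, and 199 on silica 4, against 69.0 to 76.2 on the other silica arrays. Without both arrays 5 genes were called, and the 11 that lost their calls kept 85.7% to 103% of their log2 fold change, so the loss was of calls and not of size. Of the 25 pairs of 1 control and 1 silica array, 8 left 5 or fewer calls when removed, but 6 of these 8 hold a bright array, so this count does not bear against brightness as was planned. Of the 9 pairs with a bright array 6 left 5 or fewer calls, and of the 16 pairs without a bright array 2 did. Over the 25 pairs the median was 7 calls, and the lowest count, 3, came from leaving out control 1 and silica 1, neither of them bright. Pairs with control 4 left 11 to 18 calls and mostly hold no bright array, which tilts the contrast between the 9 and the 16 pairs. Brightness of the 2 arrays and the smaller number of arrays both stay open, since each group has 1 bright array.

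Silica 4 had a median of 18.5 beads per gene, against 20 on the other silica arrays. Among single genes, RELB had a log2 signal of 6.02 in control 2 against 5.87 to 5.89 in the other controls, NPC1 had 8.08 in control 1 against 8.47 to 8.59, and ACTA2 had 10.08 in control 5 against 9.52 to 9.60. In control 4, KIF11 had 9.03 against 8.75 to 8.79 and ISG20 had 8.30 against 9.26 to 9.54. With silica, FOSB had 9.19 in silica 3 against 9.47 to 9.59, STC1 had 8.15 in silica 5 against 8.59 to 8.73, and ID2 had 8.97 in silica 4 against 8.59 to 8.70.

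No other split of the arrays that was drawn gave counts as large as the comparison did. Regrouping cannot exclude a chance difference between cultures, since the replicates may be technical. For genes lower and for lists the margin over the highest other split was small. Of 100 splits of the 10 arrays into 5 and 5, 1, the real one, gave as many changed genes (16, highest other 1), as many higher (14, highest other 1), as many lower (2, highest other 1) and as many changed at least 1.5-fold (16, highest other 1). The same held for the 14 gene lists, where the highest other split called 12, and for the 3 lists with an estimated correlation, where the highest other called 0. The split with 12 lists kept control 1, 3, 4 and 5 together and put silica 1 with them. It differs from the real split by 1 exchanged pair of arrays, so its lists can follow the treatment in part. The small margin for lists therefore comes from a split close to the real one. Splits that kept only 3 controls together called at most 3 lists each. Camera with a preset correlation thus also called lists, though few, in splits further from the treatment.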

How the results depend on the processing

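The settings for the bright arrays, for control 4 together with them, for the rows that set the background and for the signal and 1-array filters were chosen after seeing the data. In 26 alternatives no named gene and no gene list reversed its call. FOSB, CXCL8 and EGR1 were called in all 26, and every called gene that an alternative tested kept its direction. Where arrays were left out, that direction was fixed in advance by groups that do not overlap. Over the named genes 1289 values kept their side of the threshold, 77 lost it and 3 gained it, and over the lists 672 kept it, 44 lost it and 11 gained it. The immediate early, cytokine, ERK and NF-kB lists were called in all 26. Estimated correlation called the first 3 of these lists but not NF-kB (camera adjusted p = 0.0511), and fry called 9 lists, in place of 14.

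Median centring left 3 genes changed, 3 higher, 0 lower and 3 changed at least 1.5-fold, with 89 genes at an unadjusted p under 0.05 against 505. It aligned the median of all 37846 rows, most of them undetected, and left the median log2 fold change of the tested genes at 0.09. List medians under median centring are to be read against that 0.09. The cause of the lost calls was not tested. The authors' processed values called 14 genes, 10 of them changed at least 1.5-fold, on a scale compressed near background, and inference of the background from all rows left 9 changed at least 1.5-fold. Detection in all 10 arrays and array weights each gave 4 genes lower in place of 2, of 14 and 20 called. Leaving out 1 array gave 12 to 18 genes changed, 12 to 15 higher, 0 to 3 lower, 12 to 17 changed at least 1.5-fold and 10 to 15 lists, and no gene lower was called without control 2, silica 3 or silica 4. Without the 2 bright arrays 5 genes changed, 5 higher, 0 lower and 5 at least 1.5-fold, and the same counts held without control 4 as well, with 8 lists, on 8 and 7 arrays.

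The same-number correlations of deviations from the group means were 0.00, 0.17, 0.04, -0.08 and -0.08, so most replicate numbers showed no pairing. Only control 2 correlated best with the silica array of its own number. Low correlations cannot show that the design was unpaired, which the labels leave open. With the replicate block 9 genes changed, 9 higher, 0 lower and 9 changed at least 1.5-fold, and 14 lists were called. A chip block was not run. Low signal over background limits FOS and CXCL2, and 1048 rows of several probes had signal above the floor but were left out by the detection filter.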

Other observations

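The test on genes detected only with silica was set before its result was seen, and the genes singled out from the alternatives were chosen after their values were seen. Antioxidant and metal defence genes were not called as lists with the detection filter. The NRF2 antioxidant genes had a median log2 fold change of -0.06 (22 tested, camera adjusted p = 0.286; called in 1 of 26 alternatives, with no detection filter, at a median of -0.07 and adjusted p = 0.0495), with no member past the threshold over all genes or adjusted over the list alone. HMOX1, the inducible heme oxygenase, had 0.33 ± 0.19 SE (limma adjusted p = 0.863), and ME1, a cytosolic NADPH-producing enzyme, had -0.89 ± 0.27 SE (limma adjusted p = 0.545). The metallothionein and metal response genes had a median of 0.20 over 6 genes (camera adjusted p = 0.205), and lay at -1.37 in control 4 relative to the other controls. The zinc transporter SLC39A10 had the smallest p among them (0.55 ± 0.32 SE). Inflammasome components were barely covered, with 3 genes tested, a median of 0.09 against a camera direction of lower, and an adjusted p of 0.887, and the pore-forming GSDMD had -0.33 ± 0.16 SE.

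Cholesterol synthesis genes had a median of 0.14 over 21 genes (camera adjusted p = 0.0563) and were called without control 4 (median 0.16, adjusted p = 0.00276) and without silica 1 (median 0.16, adjusted p = 0.0164), with median centring (median 0.21, adjusted p = 0.0215), with array weights (adjusted p = 0.00916), with no detection filter (adjusted p = 0.0251) and with detection in at least 1 array (adjusted p = 0.0352). It was thus called in 6 of 26 alternatives, with adjusted p from 0.00276 to 0.479 over 26 alternatives. FDPS of that list had 0.43 ± 0.23 SE. The TGF-beta response and EMT genes had a median of -0.10 over 16 genes (camera adjusted p = 0.0563; 0.02 with median centring) and were called without control 2, without silica 2 (medians -0.20 and -0.11, adjusted p = 0.0206 and 0.0297) and with the bright arrays as a block (adjusted p = 0.0406; up to 0.815 over 26 alternatives). ID2, an inhibitor of helix-loop-helix factors, fell adjusted over that list alone and over the short-lived transcription and RNA control genes alone (-0.65 ± 0.18 SE, limma adjusted p = 0.425 over all genes). The glycolytic regulator PFKFB3 fell adjusted over the hypoxia list alone (-0.45 ± 0.12 SE, limma adjusted p = 0.425 over all genes). As lists, the short-lived genes (17 tested, median 0.09) and the hypoxia genes (16 tested, median -0.07, and 0.03 with median centring) were not called, with camera adjusted p = 0.275 and 0.107. With no detection filter the short-lived genes were called (median 0.09, adjusted p = 0.0215), the only such call in 26 alternatives, and the hypoxia genes were called in 0 of 26.

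The lists left uncalled also included the lysosome and autophagy genes (23 tested, median 0.07, camera adjusted p = 0.205), in which the cholesterol transporter NPC1 had 0.43 ± 0.13 SE, and the scavenger and particle uptake receptors (10 tested, median -0.08, camera adjusted p = 0.434), in which SCARA3 had -0.20 ± 0.12 SE. Type I interferon response genes had a median of 0.13 over 9 genes (camera adjusted p = 0.286), with 0.45 ± 0.20 SE for ISG20. Oxidative phosphorylation genes had 0.08 over 28 genes (camera adjusted p = 0.405), and COX6C had 0.53 ± 0.21 SE. YAP and SRF targets had -0.07 over 15 genes and housekeeping genes -0.03 over 13 (camera adjusted p = 0.542 for both), with -0.21 ± 0.13 SE for ACTA2 and 0.22 ± 0.11 SE for RPLP0. With median centring the medians of the NRF2, scavenger, YAP and housekeeping lists were 0.08, 0.06, 0.04 and 0.10. The median of all tested genes was itself 0.09 in that setting.

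Several genes were called only under an alternative. Without the detection filter KLF6, a zinc finger transcription factor, was called higher (0.65, limma adjusted p = 0.0476), with a detection p under 0.01 in 1 control and 2 silica arrays. FST, the activin antagonist follistatin, was called higher under looser filters (0.93, limma adjusted p = 0.00665 to 0.00845), with detection in 1 control and 3 silica arrays. The signals of both genes, whose rows hold several probes, lay above the floor on all 10 arrays, at 8.04 or more for KLF6 and 6.86 or more for FST against a floor of at most 5.47. HSPA1B was called lower in the authors' processed values (-0.44, limma adjusted p = 0.0250), without background correction (-0.44, limma adjusted p = 0.0452) and with background inferred from all rows (-0.56, limma adjusted p = 0.0338). CASTOR3P and GPX8 came close to the threshold (-0.79 and -0.69, limma adjusted p = 0.0622 and 0.0661), and each was called lower in several alternatives. HBP1 and AKAP8L, the latter detected in 1 of 5 control arrays, were called higher without control 4 (0.53 and 0.89, limma adjusted p = 0.0413 and 0.0129). With all arrays they had 0.48 and 0.69 (limma adjusted p = 0.226 and 0.496). Control 4 itself lay at 0.42 for HBP1 and 1.12 for AKAP8L on the scale from control (0) to silica (1). Its removal therefore raised both folds.

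A hypothesis was that silica switched on transcripts otherwise under the detection limit. Among rows of 1 probe, 10 genes were detected in 4 or 5 silica arrays and in no control array, and 3 the other way round. Of 100 splits of the arrays 32 gave as many genes detected in only 1 of the groups, with 25 in the highest other split, so the count argues against such a switch as a broad effect.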
